A study of Sus scrofa with 8 samples.

How the data were processed

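Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in porcine muscle satellite cells, the resident stem cells of skeletal muscle. The labels give 4 groups of 2 libraries, named WT and CBP at 0 h, labelled as proliferation, and at 60 h, labelled as differentiation. The treatment protocol in the labels names SGC-CBP30, a small molecule that binds the bromodomains of the acetyltransferases CBP and EP300, given for 48 h in proliferation and 60 h in differentiation. The labels do not state that the CBP groups are the treated ones, so the groups are called CBP and WT as labelled. The labels name the cell line C3H, while the organism is given as pig and the peak coordinates are those of the pig genome.

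Per the submitters' processing notes, reads were trimmed with Trimmomatic and peaks were called with MACS2 2.1.0 on the Sscrofa11.1 build. The aligner, the removal of duplicate and mitochondrial reads, and any shift of reads for the transposase are not given in the sources used here. A different handling of duplicates or of the shift would change peak heights and edges. The authors deposited a separate peak list for each library, so replicates can be compared. For each peak the deposited lists give a score, a fold enrichment over local background, a −log10 p-value and a −log10 q-value, all made by the authors' peak caller. These values belong to the authors, and they were used within a list to describe, rank or filter its peaks and to recover pileups. Their fold was also compared between libraries, as 1 of 5 forms of peak strength.

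The deposited lists hold no read totals. Under the peak caller's formulas, the fold is the summit pileup plus 1 over the local background plus 1, and the p-value is a Poisson upper tail. Both were solved together for each peak, and a whole pileup came out for 100% of peaks at a tolerance of 0.01 in −log10 p. The most frequent background value of a library, its floor, was taken as a measure of relative depth. It was 1.69 and 2.09 times that of the shallowest library in the WT 0 h libraries, and 1.98 and 1.43 times in the CBP 0 h libraries. In the 60 h libraries it was 1.11 and 1 for WT and 1.21 and 1.08 for CBP. A deeper library allows weaker peaks to be called, so the 0 h lists reach weaker sites than the 60 h lists.

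Peaks on chromosomes 1 to 18 and X were merged over the 8 libraries wherever they overlapped by 1 bp, which gave 178498 regions. A region was called in a library if any peak of that library overlapped it. A region was counted as opened when it was called in both libraries of the later or CBP group and in neither library of the reference group, and as closed in the reverse case. Each count was set beside the counts of the 2 other splits of the same 4 libraries. Counts over all 8 libraries used regions called in 4 of 4 libraries on one side and none on the other. Peak number, covered length, peak width and genomic position were compared between times with a two-sided exact permutation test over 8 libraries. A comparison of 2 libraries with 2 cannot go below an exact p = 0.333, so WT and CBP within one time are given as values. Over all 8 libraries, labels were also exchanged within each time, a test outside the original plan, whose 36 arrangements cannot go below an exact p = 0.0556. Nothing in the labels says that replicates came from separate animals or cultures, so a p-value measures only the spread between these libraries, which may be technical.

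No genome sequence was used here, and the planned search for 16 motifs was not run. The RefSeq gene table for Sscrofa11.1 gives gene starts and ends without strand, exons or introns. The plan linked regions to transcription start sites. With no strand given, each region was linked instead to the nearest end, at either side, of a protein-coding gene within 50 kb, a definition chosen after the gene table had been seen. This linked 64.4% of regions to 17509 genes. Peaks were placed by their summit within 1 kb of a gene end, elsewhere inside a gene, or between genes.

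The 16 gene lists were fixed before the data were examined. They cover myogenic regulators, satellite cell and Notch genes, sarcomere and contraction, myoblast fusion and adhesion, cell cycle, mitochondria and oxidative metabolism, acetyltransferase and bromodomain proteins, AP-1 and immediate early genes, TGF-beta and BMP targets, inflammatory and NF-kB genes, fibroblast and matrix genes, adipogenic genes, housekeeping genes, and markers of endothelial, immune and neural or Schwann cells. Of 381 list entries, 357 matched a gene and 352 had a linked region. For each list, the difference between groups in the share of libraries with a call was averaged over regions of a gene and then over genes. This mean was compared, two-sided, by a permutation of genes, not of libraries, with 10000 random gene lists matched on number of linked regions, with Benjamini-Hochberg adjustment over the 16 lists of a comparison. Genes are not replicates, so this test describes these libraries. Named genes followed a rule fixed in advance. It took the 6 genes with the most net opened and the 6 with the most net closed regions, up to 3 members of each list with the largest net number, the genes MYOD1, MYF5, MYOG, PAX7, CREBBP and EP300, and the 3 opened and 3 closed regions with the highest −log10 q in their weaker library. Some genes that this rule names are not reported here.

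Alternatives fixed in advance were a −log10 q of at least 5, the same number of peaks in every library (the 82696 with the highest −log10 p), a region called only when 50% of it was covered, links within 10 kb or within 1 kb, gene ends within 3 kb, replicate number as a block, and leaving out each replicate. Alternatives chosen after seeing the data were thinning every library to the depth of the shallowest, matching random lists also on call share, and 4 further forms of peak strength. Thinning drew a binomial sample of the recovered summit pileup of each called peak and scaled its background to match. Peaks with a −log10 p of at least 2.98 were kept at their width and position, and no peaks were called again from reads. Counts of regions and list tests under several of these settings were viewed before the final tables were made, and the main setting stayed as planned. On simulated data, 100% of opened and closed regions were recovered for WT 60 h against WT 0 h. These regions were set as called or not called in whole groups, without missed calls or a depth difference. Their recovery therefore checks the counting only, not the detection of changes in libraries like these. Of simulated lists without a change, 5.0% had p under 0.05, and of lists shifted by 13.1 percentage points 90.0% did. Links and region values of these lists were simulated, independently between regions, and not taken from these libraries. The rate therefore does not tell how often a smaller excess, or one in a smaller list, would be found. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.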

Results

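ATAC-seq peaks were compared across 8 libraries of porcine muscle satellite cells, 2 each for WT and CBP at 0 h, labelled as proliferation, and at 60 h, labelled as differentiation. The series title names CBP and the differentiation of these cells as its subject. CBP, encoded by CREBBP, is a histone acetyltransferase. The lists held 127394 and 134181 peaks for WT 0 h, 135528 and 121757 for CBP 0 h, 86282 and 82696 for WT 60 h, and 88871 and 87977 for CBP 60 h on chromosomes 1 to 18 and X. Relative depth, recovered from the authors' fold and −log10 p, was 1.80 ± 0.298 (SD, n = 4) at 0 h and 1.10 ± 0.0857 (SD, n = 4) at 60 h, in units of the shallowest library. Replicates shared between 0.635 and 0.710 of their covered bases (Jaccard index). Libraries of the same time and other label shared 0.563 to 0.684, and libraries of the same label and other time shared 0.466 to 0.530. These values carry the difference in peak number between the times. With the same number of peaks in every library, the index over regions was 0.702 to 0.803, 0.611 to 0.752 and 0.599 to 0.671, in that order. In that setting WT 60 h libraries shared more with WT 0 h (0.649 to 0.671) than with CBP 60 h (0.611 to 0.629). The order was reversed for CBP 60 h libraries, which shared less with CBP 0 h (0.599 to 0.610) than with WT 60 h.

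The comparison of times asked how accessible chromatin differed between proliferation and differentiation. Libraries at 60 h had fewer, narrower peaks that lay more often at gene ends. Peak number was 129715 ± 6389 (SD, n = 4) at 0 h and 86457 ± 2727 (SD, n = 4) at 60 h, a ratio of 0.667 (two-sided exact permutation test, p = 0.0286, the smallest that 8 libraries allow). Covered length was 92.2 ± 7.02 Mb (SD, n = 4) at 0 h and 54.7 ± 2.18 Mb (SD, n = 4) at 60 h, and median peak width was 598 bp and 532 bp (exact permutation p = 0.0286 for each). The share of summits within 1 kb of a gene end was 11.5% ± 0.435 (SD, n = 4) at 0 h and 15.3% ± 0.358 (SD, n = 4) at 60 h (exact permutation p = 0.0286). With the same number of peaks in every library, these shares were 14.96% and 15.7%. After thinning to 1 depth, an alternative chosen after seeing the data, peak numbers were 120456 ± 2413 (SD, n = 4) and 85856 ± 2250 (SD, n = 4).

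**Figure D1:**
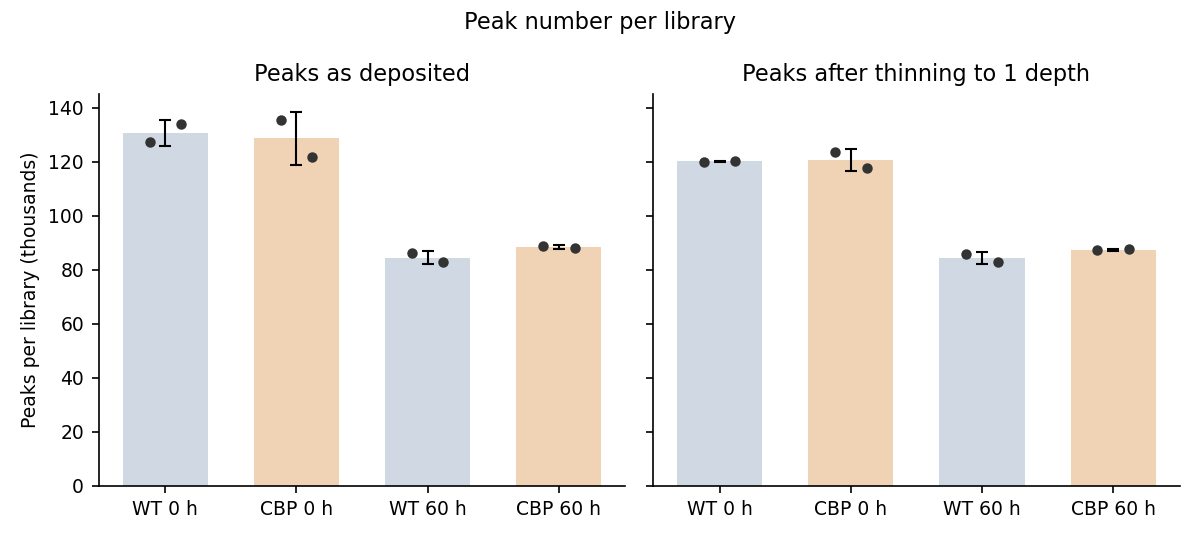
Peaks per library for the 4 groups, as deposited (left) and after thinning to 1 depth (right). Bars are means of 2 libraries, error bars are SD and points are libraries, and every 60 h library lies below every 0 h library in both panels.

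Between WT 0 h and WT 60 h, the genes with the most closed regions had 9 to 12 each. Over all genes, 16429 of 114921 linked regions closed and 661 opened, and a rank by number favours genes with many linked regions. PAX7, the transcription factor that marks satellite cells (chromosome 6, 77160827 to 77268626), had 9 closed and 0 opened of 42 linked regions. MET, the receptor of hepatocyte growth factor (chromosome 18, 29426044 to 29541526), had 12 closed of 28. PARP8 had 12 closed, ZNF608 had 11 and SMAD6, an inhibitor of BMP signalling, had 9, each with 0 opened. The highest net number for these genes under the other splits of the 4 libraries was 1. With the same number of peaks in every library, ZNF608 had 6 closed and 1 opened regions, MET 5 and 1, PAX7 3 and 1, PARP8 1 and 0, and SMAD6 0 and 0.

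Over the genome, 26884 regions closed and 1168 opened between WT 0 h and WT 60 h. The other splits gave at most 1381 regions in 1 direction, which the closed count exceeded and the opened count did not. Each side of these splits holds 1 library of each time, so they count only replicate differences that recur at both times. They do not measure all differences between replicates, whose Jaccard index over regions was 0.754 in WT 0 h and 0.700 in WT 60 h. With the same number of peaks in every library, 7590 regions closed and 4837 opened. In the CBP libraries, 26552 regions closed and 3247 opened between the times, with at most 2016 in 1 direction under the other splits. Over all 8 libraries, 10145 regions were called in every 0 h library and no 60 h library, and 233 in the reverse case.

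Genes with the most opened regions in the WT comparison had 2 or 3 each. COL1A1, the alpha 1 chain of type I collagen (chromosome 12, 26379087 to 26397180), had 2 opened and 0 closed of 13 linked regions, and its net was 0 under the other splits. PLOD2, a lysyl hydroxylase that modifies collagen, and OXR1 each had 2 opened and 0 closed, against a net of 1 under another split. GAS1 had 3 opened and 1 closed regions, and its net was -1 at a −log10 q of at least 5. PRRX1 had 2 opened and 0 closed, and its net was -2 when 50% of a region had to be covered.

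Among the myogenic regulators, the transcription factors that direct muscle differentiation, 8 of 13 genes had net closed and 1 had net opened regions, where 8774 of all 17509 genes had net closed regions. The list had 20 closed and 1 opened of 143 linked regions, and 5 of each with equal peak numbers. MYOG, which drives terminal differentiation, had 1 opened and 0 closed of 10, within the other splits, and a net of -1 at a −log10 q of at least 5. MYOD1 had 0 opened and 0 closed of 8, and MYF5 had 1 closed of 5. MYF6 had 3 closed and EYA1 had 4. Satellite cell and Notch genes had 62 closed and 1 opened regions, with 17 of 22 genes net closed, among them SPRY1, an inhibitor of receptor tyrosine kinase signalling, with 6 closed. Their mean change in share of libraries with a call was -30.3 percentage points, against -25.1 in random lists (adjusted permutation p = 0.24).

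The AP-1 and immediate early list, transcription factors and feedback regulators induced rapidly by growth signals, was the list whose change differed from that of random lists. Its mean share fell by 10.3 percentage points, against -24.3 in random lists (excess 14, adjusted permutation p = 0.0032 over 16 lists). It had 19 closed and 1 opened regions, with 11 of 21 genes net closed and 10 neither. Its direction turned with the same number of peaks in every library, to 5 closed and 10 opened. DUSP6, a phosphatase of ERK, had 3 closed of 17. MYC had 3 closed of 12 and FOS had 2 closed of 18, and with equal peak numbers both had a net of 1 opened. The list's excess was 5.45 points in that setting (adjusted permutation p = 0.46), 10.8 with links within 1 kb (adjusted permutation p = 0.25), and 11.13 without WT 0 h replicate 2 (adjusted permutation p = 0.11). When random lists were also matched on call share, chosen after seeing the data, it was 8.61 (adjusted permutation p = 0.051). Over all settings the excess lay between 5.45 and 18.6 points, with an adjusted permutation p from 0.0008 to 0.46. Over the 8 libraries its share above that of all linked regions was 8.67 points at 0 h and 15.1 points at 60 h (exact permutation p = 0.0571, adjusted permutation p = 0.183). In this test no list passed, and AP-1 did not rank first. Fibroblast and matrix genes (-1.13 and 3.98 points) and inflammatory and NF-kB genes (-0.409 and 4.16) each had an exact permutation p = 0.0286 (adjusted permutation p = 0.183). With equal peak numbers the exact permutation p was 0.257 for AP-1, 0.0286 for fibroblast and matrix and 0.914 for inflammatory and NF-kB genes.

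The other lists did not pass the threshold (adjusted permutation p from 0.24 to 0.99), and several no longer had more closed than opened regions with equal peak numbers. Equal peak numbers gave 11 closed and 25 opened regions for fibroblast and matrix genes, 5 and 10 for adipogenic genes, 3 and 7 for endothelial markers, 8 and 10 for myoblast fusion and adhesion, 11 and 11 for sarcomere and contraction, and 25 and 7 for satellite cell and Notch genes. Counts in the rest of this paragraph are from peaks as deposited unless equal peak numbers are named. For comparison, 16429 of the 114921 linked regions of all genes closed and 661 opened in WT as deposited. Sarcomere and contraction genes had 49 closed and 3 opened of 352 linked regions, including 5 closed at MYOM1 and 4 at the calcium store protein CASQ2. Myoblast fusion and adhesion genes had 38 closed and 3 opened of 267, including 6 closed at the cell surface receptor CDON and 5 at the cadherin CDH2. Fibroblast and matrix genes had 45 closed and 8 opened, with an excess of 6.07 points (adjusted permutation p = 0.24). That excess passed with equal peak numbers (10.2, adjusted permutation p = 0.029), at 50% coverage (14.1, adjusted permutation p = 0.0008) and after thinning (8.68, adjusted permutation p = 0.030), and was 2.67 without WT 60 h replicate 1 (adjusted permutation p = 0.83) and 1.5015 with links within 1 kb (adjusted permutation p = 0.93). Cell cycle genes had 19 closed and 2 opened of 150, including 3 closed at CCND1 and 2 at CDK1. Acetyltransferase and bromodomain genes had 39 closed and 1 opened, including 5 closed at CREBBP, while EP300 had 1 closed of 8. TGF-beta and BMP targets had 31 closed and 0 opened, inflammatory and NF-kB genes 38 and 4, adipogenic genes 27 and 3, mitochondria and oxidative metabolism genes 16 and 2, and housekeeping genes 11 and 1. Markers of other cell types had 25 closed and 0 opened regions for endothelial cells, 7 and 0 for immune cells, and 16 and 0 for neural and Schwann cells. In CBP between the times no list passed (adjusted permutation p from 0.35 to 0.95), and fibroblast and matrix genes had 52 closed and 9 opened regions (excess 7.23 points, adjusted permutation p = 0.35). With equal peak numbers they had 18 closed and 23 opened regions and passed (excess 11.3, adjusted permutation p = 0.030).

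The strongest closed region of the WT comparison lay inside ERC2 on chromosome 13, from 38083636 to 38085165, with an authors' −log10 q of 38.3 in its weaker WT 0 h library. The next lay inside CADM1, a cell adhesion molecule, on chromosome 9 from 42969029 to 42970525, and inside NRDE2 on chromosome 7 from 112078570 to 112079581. The ERC2 region was still called in CBP 60 h replicate 1 and the CADM1 region in CBP 60 h replicate 2. Only the NRDE2 region was called in no 60 h library. The strongest opened region lay inside KCNJ6, a potassium channel gene, on chromosome 13 from 201298658 to 201299327, with a −log10 q of 14.8, and was called in no CBP library. An opened region on chromosome 5 from 93555116 to 93556240, between genes and 247606 bp from DUSP6, was called in all 4 libraries at 60 h.

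**Figure D2:**
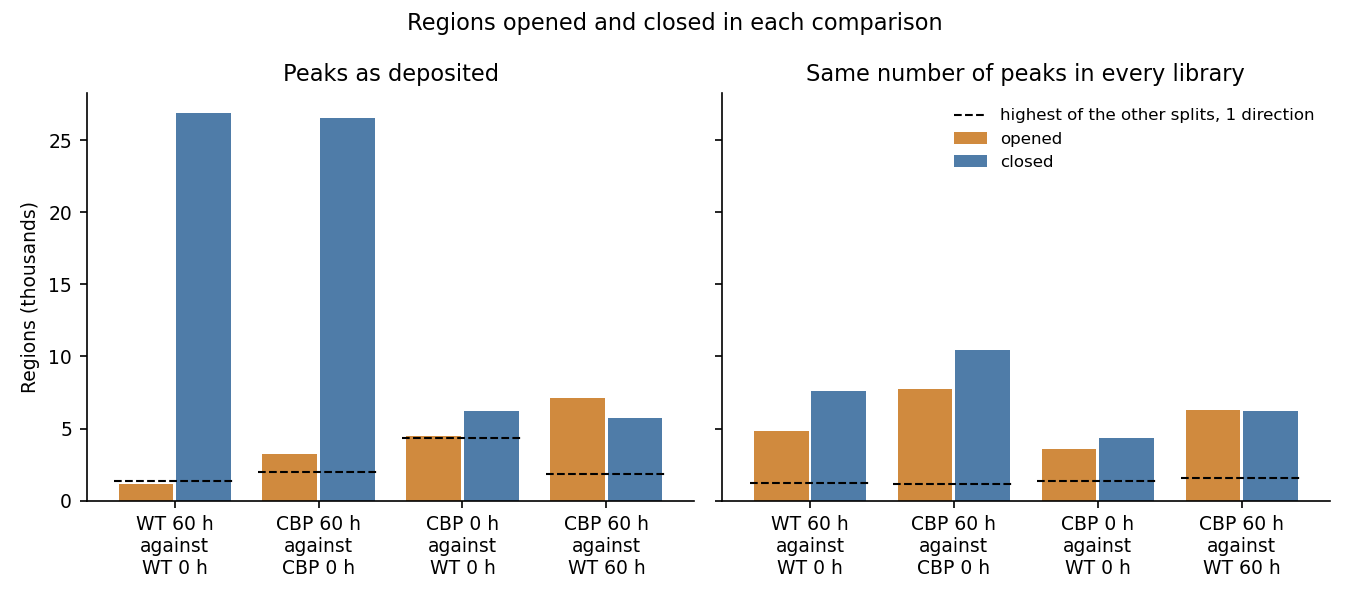
Numbers of opened and closed regions for 4 comparisons, with peaks as deposited (left) and with the same number of peaks in every library (right). Dashed lines are the highest count in 1 direction under the other splits of the same 4 libraries, which the 1168 opened regions of the WT comparison as deposited do not reach, and the 4837 with the same number of peaks do.

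The comparison of CBP with WT at 0 h asked how the labelled groups differed in proliferating cells. Closed regions were led by ATF6, a transcription factor of the endoplasmic reticulum stress response (chromosome 4, 88591279 to 88806156), with 5 closed of 19, by DYNC2H1, a motor protein of cilia, with 5 closed of 13, and by PARP8, with 5 closed and 1 opened of 34. PARP8 turned to 1 closed and 2 opened with equal peak numbers. AKT2, a kinase of insulin signalling, MAP4, a microtubule-binding protein, and TLN2, a talin, each had 4 closed. MEP1B (chromosome 6, 116015021 to 116049796) and REEP1 each had 4 opened and 0 closed, and SLC6A6, a taurine transporter, had 3 opened. RUNX1 also had 3 opened and 0 closed. These numbers were also lower with equal peak numbers, with 1 closed region each for ATF6, DYNC2H1, AKT2 and MAP4 and 2 for TLN2, and 2 opened for REEP1, 1 each for MEP1B and RUNX1 and 0 for SLC6A6.

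In total 4474 regions opened and 6194 closed in CBP at 0 h, a sum of 10668 against 5356 in the highest other split, which gave up to 4335 in 1 direction. Peak number differed little, with a CBP to WT ratio of 0.984 (n = 2 each). Without CBP 0 h replicate 2, 17171 regions were called in the remaining CBP library and in neither WT 0 h library, and without WT 0 h replicate 1, 16543 were closed.

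No list passed the threshold at 0 h (adjusted permutation p from 0.13 to 0.99), and 2 lists had an unadjusted p under 0.05. Acetyltransferase and bromodomain genes had 11 closed and 2 opened regions, with an excess of -8.58 points (permutation p = 0.0082, adjusted permutation p = 0.13). KAT7 and NCOA1, both linked to histone acetylation, had 3 closed regions each, and EP300 had 1. This list passed after thinning (excess -11.2, adjusted permutation p = 0.0080) and when random lists were also matched on call share (excess -8.40, adjusted permutation p = 0.029), both alternatives chosen after seeing the data. Among settings chosen before the data were examined, its excess was -2.96 with equal peak numbers (adjusted permutation p = 0.61), -4.20 with links within 10 kb (adjusted permutation p = 0.59) and 2.17, of opposite sign, with links within 1 kb (adjusted permutation p = 0.93). Sarcomere and contraction genes had 20 closed and 11 opened regions (excess -5.18, adjusted permutation p = 0.32), including 2 closed at MYH7 and 2 at MYL1. Myogenic regulators had 7 closed and 3 opened (excess -5.84, adjusted permutation p = 0.57), with 1 closed at MYOG and 1 at MYF5. PAX7, MYOD1 and CREBBP had 0 opened and 0 closed.

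The strongest opened regions lay inside CLSTN2 on chromosome 13, from 80863130 to 80864170, and between genes on chromosome 16, from 17493397 to 17494132, where CDH6 was the nearest gene. The second was called in all 4 CBP and no WT libraries. The strongest closed regions lay inside MCUB on chromosome 8 from 112594169 to 112595242, ZNF34 on chromosome 4 from 124413 to 125256, and FRYL on chromosome 8 from 38422896 to 38424017. All 3 were called in all 4 WT and no CBP libraries.

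At 60 h, the comparison of CBP with WT asked how the groups differed in differentiation. ANKFN1 (chromosome 12, 32479469 to 32823527) had 8 opened and 1 closed of 24 linked regions, LHFPL2 had 6 opened and NRP2, a semaphorin receptor (chromosome 15, 108974246 to 109092316), had 5. SLIT1, an axon guidance ligand, had 4 opened and BMP2 had 3. Closed regions were led by AKR1B1, an aldose reductase, the actin-associated protein PALLD, BASP1 and GSAP, with 4 each and 0 opened. COL15A1, a collagen chain (chromosome 1, 240718128 to 240829188), had 4 closed of 33, and COL1A1 had 3 closed of 13. At a −log10 q of at least 5, ANKFN1 had 1 opened region, SLIT1 and BMP2 had 0 opened, and COL1A1 had 0 closed.

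In total 7149 regions opened and 5702 closed in CBP at 60 h, a sum of 12851 against 3257 in the highest other split. Peak number had a CBP to WT ratio of 1.05 (n = 2 each), labels exchanged within both times gave an exact permutation p = 0.778, and the difference between the CBP effects at the 2 times did not pass (exact permutation p = 0.444). Leaving out 1 library gave 10172 to 17229 opened and 8826 to 13179 closed regions. The share of summits inside genes but not at gene ends was 48.1% ± 0.227 in WT and 47.2% ± 0.143 in CBP at 0 h, and 45.6% ± 0.295 and 44.4% ± 0.178 at 60 h (SD, n = 2 each). Between genes it was 40.5% ± 0.0147 in WT and 41.2% ± 0.547 in CBP at 0 h, and 38.9% ± 0.0920 and 40.5% ± 0.306 at 60 h (SD, n = 2 each). For both shares every CBP library lay on the same side of every WT library of its time, and the exact permutation p within time was 0.0556, the smallest possible, which does not pass.

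Satellite cell and Notch genes had 19 opened and 3 closed regions at 60 h, with 12 of 22 genes net opened and 1 net closed (excess 6.35 points, permutation p = 0.013, adjusted permutation p = 0.21). SDC3, a syndecan of satellite cells, had 3 opened of 16 and HEY1, a Notch target, had 2 of 14. NOTCH2 had 2 opened of 21, and its net was -1 at a −log10 q of at least 5. With links within 1 kb of a gene end the list passed (excess 17.0, adjusted permutation p = 0.0064), as did its difference between the times (excess 18.7, adjusted permutation p = 0.042). With links within 50 kb that difference was 5.74 points (adjusted permutation p = 0.42), and it lay between 2.34 and 8.18 points when 1 library was left out. The list's excess at 60 h lay between 4.77 and 17.0 points over all settings and passed in no other (adjusted permutation p up to 0.32). PAX7 had 1 opened and 1 closed region, MYOG had 0 of either and MYOD1 had 1 closed. For the difference between the times with links within 50 kb, 2 other lists had a larger excess of the opposite sign. These were adipogenic genes (-9.38) and AP-1 and immediate early genes (-8.46, adjusted permutation p = 0.36 for each).

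With links within 50 kb no list passed at 60 h (adjusted permutation p from 0.21 to 0.89), and 2 of all 16 lists had an unadjusted p under 0.05. Sarcomere and contraction genes had 16 closed and 13 opened regions (excess -4.35, adjusted permutation p = 0.28), with 3 closed at MYBPC1, a myosin-binding protein. Myoblast fusion and adhesion genes had 12 closed and 7 opened, with 2 closed at the integrin ITGB1 and 2 opened at CDON. AP-1 and immediate early genes had 8 closed and 4 opened (excess -5.86, adjusted permutation p = 0.28). Neural and Schwann markers had 3 opened and 1 closed (excess 10.2, adjusted permutation p = 0.28) and endothelial markers 7 opened and 5 closed (excess 5.73, adjusted permutation p = 0.28). Both marker lists passed when 50% of a region had to be covered (excess 18 and 13, adjusted permutation p = 0.024 for each). At a −log10 q of at least 5 their excess was -0.959 and -0.419 (adjusted permutation p = 0.93 for each), and with links within 1 kb it was -5.89 for the neural list (adjusted permutation p = 0.62).

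**Figure D3:**
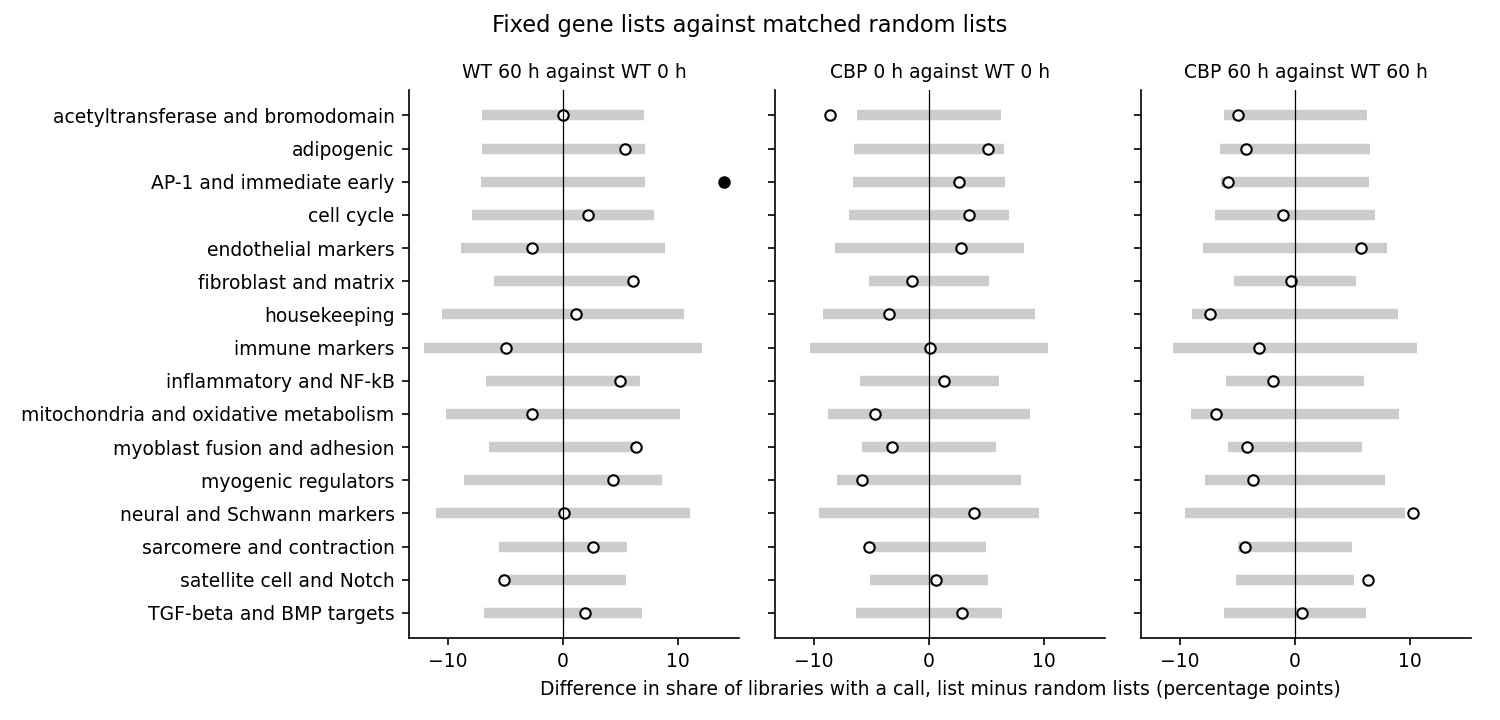
Difference of each fixed list from matched random lists, in percentage points of the share of libraries with a call, for 3 comparisons. Grey bars span 2 SD of 10000 random lists on either side, filled points passed the threshold of 0.05 after adjustment, and the AP-1 and immediate early list in WT 60 h against WT 0 h is the filled point at 14.

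The strongest closed regions at 60 h lay between genes on chromosome 14, from 82145754 to 82147013, with MAT1A nearest, and on chromosome 5, from 87657263 to 87658135, with NTN4 nearest. Both were called in every library except the CBP 60 h ones. The strongest opened region inside a gene with a symbol lay in DLG2 on chromosome 9, from 19411542 to 19412205, and was called in all 4 CBP and no WT libraries.

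Regions whose call differed between the times in 1 pair of WT libraries were then followed in the libraries not used to choose them. Of opened regions, 32.0% were called in the held-out WT 60 h library and 29.7% in the CBP 60 h libraries, the mean of 4 choices of pair, with CBP lower in 4 of 4. The held-out WT 0 h library held 29.6% of them and the CBP 0 h libraries 25.9%, so CBP was also lower than WT at 0 h. With peaks as deposited, the held-out WT share of opened regions thus differed little between 0 h and 60 h. The lower CBP share at 60 h in this setting therefore cannot be read as a loss of differentiation regions. Of closed regions, 18.97% were still called in the held-out WT 60 h library and 23.4% in the CBP 60 h libraries, with CBP higher in 4 of 4. At 0 h the held-out WT library held 69.8% of them and the CBP libraries 64.8%. With the same number of peaks in every library, the shares at 60 h were 46.6% and 41.7% for opened regions and 31.2% in both for closed regions. At 0 h they were then 21.2% in WT and 22.0% in CBP for opened regions, and 67.8% and 63.3% for closed regions. With equal peak numbers the WT 60 h replicates shared more regions with each other (index 0.706) than with CBP 60 h (0.611 to 0.629). Regions chosen in 1 WT 60 h library therefore favour the other one, so the lower CBP share of opened regions is not specific to differentiation regions there either. The 4 choices share libraries and are not independent, and no test was run on them.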

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

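The tests of peak strength and the thinning to 1 depth were chosen only after the peak numbers had been seen. Peaks outside chromosomes 1 to 18 and X, which no comparison used, numbered 825 to 1267 per library.

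The first pattern is the lower number of peaks at 60 h. After thinning to 1 depth the ratio of 60 h to 0 h was 0.713, with every 60 h library below every 0 h library. Closed regions still outnumbered opened regions 14.2 to 1 in WT. As far as thinning of called peaks can show, these values argue against lower depth of the 60 h libraries as the whole cause. Peaks were not called again from fewer reads, so the losses that a truly lower depth would bring may differ. Weaker enrichment of peaks over background in the 60 h libraries cannot be told apart from a loss of open sites. Peak strength at the 50575 regions called in all 8 libraries was computed in 5 forms, of which depth does not set 3. The pileup over the genome floor had a ratio of 0.845 and the local background over that floor 0.831. In both of these, every 60 h library lay below every 0 h library. The pileup over local background had a ratio of 1.02, and its libraries overlapped (6.68 to 7.30 at 0 h, 6.82 to 7.31 at 60 h). It is the only one of the 3 that sets peaks against their local background. The 3 forms are not independent, because in each region the first is the product of the other 2. Local background over the floor is not itself a height of peaks, so the 2 lower forms are not separate evidence of weaker enrichment. The authors' fold, compared first, had a ratio of 0.936 and the summit pileup 0.518, but both depend on depth and decide nothing. A change of chromatin with differentiation stays open, as does a difference in library quality between the times.

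The second pattern is the set of regions that follow the time in all 8 libraries. The split by time gave 10378 regions, and 1 of the 35 splits, the real one, gave as many. That is the smallest share 35 splits allow, so a chance division of the libraries is unlikely but not excluded. Of these regions 10145 were called only at 0 h, where every library was deeper. A difference in depth or yield that follows the time could therefore also put this split first. The highest of the other splits gave 760 regions, and that split was the one by label.

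The third pattern is the set of regions that follow the label. For CBP against WT over both times, 760 regions followed the label and the highest other split gave 195. Only 1 of the 18 splits, the real one, gave as many, but 18 splits are too few for a share under 0.05. At 60 h alone, the highest of the other splits gave 0.253 times the total of the split by label. This argues only against differences between libraries that do not follow the label as the whole cause. Both other splits pair 1 WT with 1 CBP library, so they cannot show a difference that follows the label. No library batch is given in the labels, so a batch that follows the label stays open, beside an effect of whatever the CBP label stands for. The labels do not state that the CBP groups are the treated ones.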

How the results depend on the processing

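Thinning, matching on call share and the further forms of peak strength were chosen after the results had been seen. Of the values that answer a comparison, 186 stayed on their side of the threshold or within their spread or 1.5 times their count, 59 moved beyond and 2 lost significance. The replicate numbers did not pair the libraries (correlations of same-numbered deviations from -0.0127 to 0.00449). With replicate number as a block the peak ratio of 0.667 and the gene end difference of 3.80 points had an exact permutation p = 0.0556, the smallest that its 36 arrangements allow. Counts of regions do not use the block. Depth limits which weak regions can be called at 60 h.

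With the same number of peaks in every library, which by construction removes any difference in yield, opened and closed regions were 4837 and 7590 for WT between times (1168 and 26884 in the main setting) and 7744 and 10478 for CBP (3247 and 26552). Regions called in all libraries of 1 time numbered 1345 at 60 h and 2492 at 0 h, those in all WT and no CBP libraries 661 (403), held-out differences were -4.93 points for opened (-2.26) and 0.0342 for closed (4.42), and 1 list, fibroblast and matrix, passed for CBP between times. At a −log10 q of at least 5, opened regions were 633 for WT and 1882 for CBP between times, 119 regions followed 60 h (233), 231 followed CBP (357) and the held-out opened difference was -7.97, with CBP lower in 3 of 4 choices of pair (4 of 4 in the main setting). With 50% of a region covered it was -3.80, and 2 lists passed in WT between times and 2 in CBP against WT at 60 h. In WT between times 2 lists passed after thinning, 0 with links within 1 kb and 0 with matching on call share. In CBP against WT at 0 h, 1 passed after thinning and 1 with that matching. With links within 1 kb, 1 passed in CBP against WT at 60 h and 1 for the difference of CBP effects. The cause was not tested for settings other than equal numbers.

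Leaving out each library asks for fewer agreeing libraries, which raises counts by construction. Opened and closed regions then ranged from 1775 to 4474 and 33887 to 44901 for WT between times, 3912 to 9191 and 34338 to 47672 for CBP, 7603 to 17171 and 8470 to 16543 for CBP against WT at 0 h, and 10172 to 17229 and 8826 to 13179 at 60 h. Regions following 60 h ranged from 255 to 412, 0 h from 11557 to 13675, CBP from 403 to 770 and WT from 499 to 915. The number of lists passing in WT between times ranged from 0 to 1, with 0 without WT 0 h replicate 2.

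Among named genes whose net number exceeded that of the other splits, the direction reversed 28 times over these settings, 13 of them with the same number of peaks. That setting lowers closed and raises opened regions over the whole genome in WT between times, so reversals there are not specific to these genes, and the cause of the others was not tested. Genes within the other splits also changed sign and are not counted. At a −log10 q of at least 5 the net was -1 for FLT1, IDH2, SIPA1L2 and MEGF10 at 0 h and for NCOA1, MYOM1 and NOTCH2 at 60 h in CBP against WT, -2 for TPM1 and 1 for DUSP6, LIF and DOCK1 at 60 h, and -1 for GAS1 in WT between times. With the same number of peaks it was 1 for PARP8 and -1 for MEF2A and MEGF10 at 0 h, -1 for TPM1 at 60 h, and in WT between times 1 for FOS, MYC, SKI, HDAC4, FBN1, PTPRC and MEF2C and 2 for ZNF423 and CDH5. With 50% of a region covered it was -1 for FBLN2 at 0 h and HDAC4 at 60 h and -2 for PRRX1 in WT between times.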

Other observations

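Both comparisons below were chosen only after the counts of opened and closed regions had been seen. Of the 7149 regions opened in CBP at 60 h, 47.9% were called in both WT 0 h libraries and 34.2% in neither, and 1542 were called in no 0 h library. Of the 5702 closed regions, 83.0% were called in both WT 0 h libraries. Under the 2 other splits of the 60 h libraries the share in both WT 0 h libraries lay between 67.6% and 74.1%. In both CBP 0 h libraries, 56.2% of the opened and 68.0% of the closed regions were called, with 67.2% to 68.9% under the other splits. With the same number of peaks in every library the shares in both WT 0 h libraries were 19.5% for opened and 59.9% for closed regions, with 32.2% to 38.6% under the other splits. In both CBP 0 h libraries they were then 30.6% for opened and 44.1% for closed regions, with 37.7% to 40.9% under the other splits.

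Between the comparisons of CBP with WT at 0 h and at 60 h, 357 regions were opened in both and 403 closed in both. Opened at 0 h and closed at 60 h were 34 regions, and closed at 0 h and opened at 60 h were 102. If the 2 comparisons were independent over the 178498 regions, 179, 198, 143 and 248 would be expected, in that order. The 357 and 403 regions are the 760 that followed the label above, so they are not a separate result. No further test was run on these counts.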
